A study of seawater metagenome with 21 samples.

How the data were processed

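Each of the 21 samples was total RNA from plankton filtered out of seawater, labelled with Cy3 and hybridised to 1 custom Agilent array. The labels name the diazotrophic (nitrogen-fixing) symbionts Richelia intracellularis and Calothrix rhizosoleniae and list the genomes RintRC01, RintHH01, RintHM01 and CalSC01. Per the file headers and the labels, the authors extracted spot values with Agilent Feature Extraction 10.7.3.1, which gave a background-subtracted intensity per spot that was not normalized between arrays. The deposited value table of the series holds linear intensity per target with identical sorted values in all 21 columns, as quantile normalization leaves it. Its column median was 3.7. The remaining deposited columns used here were raw median intensity of the spot and of its local background, and other flags of 0 or 1 per spot.

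The slide numbers showed 2 print runs of the array. Print 1 carried 955 targets with 15 spots each and held 7 night arrays of stations 8 and 19. Print 2 carried 843 targets with 18 spots each and held 14 arrays. The analysis used the 747 targets with the same name on both prints, and 1 name used by 2 probes was left out. Targets are named by a contig and a start and end position, and the files do not pair these names with gene names, with functions or with the 4 genomes. The names fell into families, which served as lists in place of the genomes. There were 463 unprefixed targets (contig followed by a number), 246 CBZS targets (a contig name with the letters CBZS), 30 insertion sequence targets and 8 CAIS targets. The 19 function lists fixed beforehand, among them nitrogenase, photosystems and heterocyst genes, matched 0 target names and could not be tested. The comparison of the same gene between genomes could not be run for the same reason.

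A target's level on an array was the mean over its spots of log2 processed intensity, with spots that the software marked as non-uniform or as population outliers removed, so that 10 to 18 spots remained per target. Each array was scaled by subtracting the 75th percentile of its 16 targets that were detected on all 21 arrays. A target counted as detected on an array when a share of more than 0.5 of its spots was called well above background. Targets detected on at least 3 arrays were tested, which left 249, of them 134 unprefixed, 107 CBZS, 6 insertion sequence and 2 CAIS targets. Of the 747 targets, 375 were detected on no array.

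Samples were grouped by day or night and by depth, with 5 m or less as surface and 10 m or more as subsurface. A cast is a station sampled in 1 period, and there were 10 casts. The labels give different times within the station 10 night cast, 4:50 at 1 m and 2:50 at 21 m. One fit with limma 3.58.1 in R 4.3.3 held the 4 groups and the print run as fixed terms and the cast as a random block (within-cast correlation 0.370, 16 residual degrees of freedom). Contrasts were day minus night, surface minus subsurface, the difference of day minus night between layers, and day minus night within each layer. Differences between stations were tested with limma's moderated F over casts of the same period and print, with depths of a cast as the spread. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Family lists were tested with cameraPR (preset correlation 0.01, and an estimated correlation), which sets a list against the other tested targets. Fry tested each list against no change. CBZS and unprefixed targets make up nearly all tested targets. In cameraPR 1 of these lists standing lower therefore makes the other stand higher. Family means and shares of detected targets were compared by two-sided exact permutation of cast means, by exact sign flips within casts, and by exact rearrangement of arrays into casts. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

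The design, the lists, the alternatives and the rule for naming targets were fixed before the data were examined, except where the text says otherwise. The plan set lists per genome, and the name families took their place once the files were read. The plan did not hold the Fisher tests, the sign flips or the permutations of mean levels. Nor did it hold the CBZS minus unprefixed difference or the rearrangement of arrays into casts. The naming rule names the 10 targets with the smallest p where fewer than 10 pass. Because names without a gene say little, only the 2 smallest p in each direction among those 10 are printed, and the others are summarised. The rule's named genes (such as nifH and psbA) could not be found among the target names. The fit was tested on simulated data with 40 changed targets in each of 5 runs. For a change of 2 on the log2 scale it recovered 63.6% of the day versus night, 96.8% of the depth and 21.2% of the station differences. For a change of 1 it recovered 11.9%, 54.0% and 3.17%. The simulated errors were independent between targets, while real targets of a family vary together. The share of false calls among the calls lay slightly above the threshold for day versus night and below it for depth and stations. The number of arrays and casts limits the precision. The alternatives tried were quantile normalization, the median of detected targets, the percentile over all targets, centring of each family, normexp background correction (offset 50, on the median spot signal since the mean spot signal was not among the columns), the deposited value table, other detection filters, the median over spots, other terms for print, slide, cast and station, depth in m, another surface limit, and leaving out each array and each cast. The normexp offset of 50 is above the median intensity of every array, 1.11 to 7.01, and so shrinks the log2 differences of dim targets. Fits without the arrays of slides 1 and 2, a common floor, lists by contig, and the alternatives for stations, for the separate layers and for station 17 were added after the data were seen.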

Results

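The 21 arrays came from 9 stations in the South China Sea and fell into 4 groups. There were 5 day surface, 4 day subsurface, 4 night surface and 8 night subsurface samples, taken between 1 m and 37 m. They came from 5 day and 5 night casts, and 8 casts held both layers. Station 9 by day and station 21 by night were 1 array each, at 1 m and at 21 m. Station 17 was sampled in both periods. The number of detected targets ran from 23 to 280 of 747 per array. On the 5 arrays of slides 1 and 2 (station 19, and station 8 at 25 m) it was 23 to 67, and the lowest target called above background there stood at an intensity of 16.3 to 28.6, against 4.23 to 5.91 on the other arrays. Within an array the spots of a detected target had a median SD of 0.22 on the log2 scale. Levels are log2 intensities relative to the array's own percentile, and most are negative because most targets were dimmer than the bright targets that set it.

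CBZS targets were most often detected at station 17 at night, where the mean of the cast was 47.2% of the 246. The lowest mean was 4.27%, at station 19, whose 4 arrays were on the slide with the high background. By day the share of CBZS targets ran from 8.54% at station 9 to 23.6% at station 17. Unprefixed targets were detected at 12.6% to 17.0% by day and at 5.94% to 24.3% by night.

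**Figure D1:**
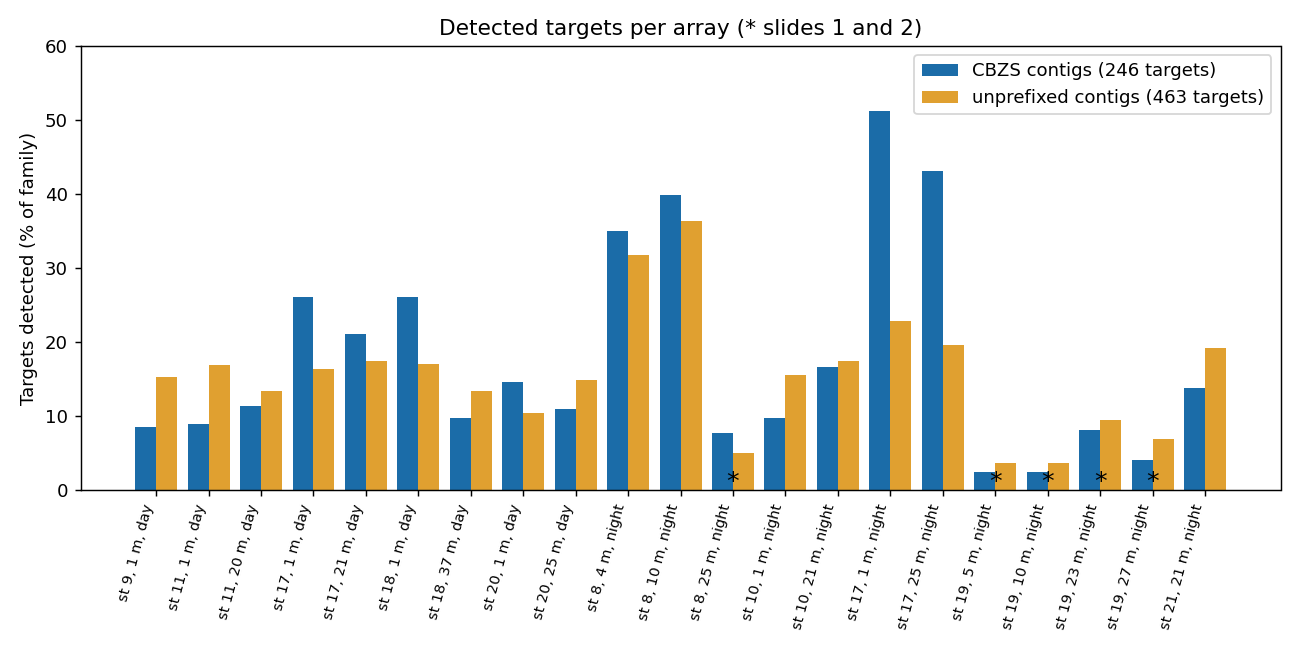
Bars give the share of CBZS and unprefixed targets detected on each of the 21 arrays (vertical axis in percent of the family, 1 bar per family and array, no error bars), ordered by period, station and depth, with a star on the arrays of slides 1 and 2. The CBZS bars are tallest at station 8 at 4 m and 10 m and at station 17 at night, and the cast mean at station 17 at night is 47.2%.

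In the comparison of day with night, the 5 night casts had on average 21.2% ± 16.7 (SD, n = 5) of CBZS targets detected and the 5 day casts 14.6% ± 6.15 (SD, n = 5). For unprefixed targets the shares were 17.5% ± 7.04 and 15.1% ± 1.55, for insertion sequences 13.3% ± 8.82 and 8.67% ± 2.74, and for CAIS targets 22.1% ± 13.6 and 25.0% with no spread. In exact permutations of the casts, two-sided, p was 0.5 for CBZS, 0.524 for unprefixed, 0.365 for insertion sequence and 0.722 for CAIS targets (adjusted over the 4 families 0.698, 0.698, 0.698 and 0.722, smallest possible 0.00794). Within print 2 alone the unprefixed share was 15.1% by day and 19.0% by night (exact permutation p = 0.0357, adjusted over the 4 families 0.143, smallest possible 0.0179). CBZS shares within print 2 were 14.6% and 24.7% (exact permutation p = 0.321). Mean levels of the tested targets by day and by night were -4.12 ± 0.29 and -3.71 ± 0.27 for unprefixed, -4.76 ± 0.23 and -4.07 ± 0.59 for insertion sequence and -4.67 ± 0.84 and -4.02 ± 0.98 for CBZS targets (SD over 5 casts each). The exact permutation p were 0.0556, 0.0556 and 0.302, adjusted 0.111, 0.111 and 0.402. Within print 2 alone they were 0.232, 0.161 and 0.554. The station 19 night cast had the highest unprefixed and insertion sequence levels of all casts, -3.35 and -3.34. Its detected shares of these families were the lowest, 5.94% and 3.33%, so its levels are mostly background values. Those values raise the night means, and print 2 alone leaves this cast out.

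Of the 249 tested targets, 0 passed the threshold for day versus night in limma, and at an unadjusted p under 0.05 there were 1 higher and 8 lower by day. The 2 lower targets with the smallest p lie on the same CBZS contig. NZ_CBZS010000259.1_4290_3247 (positions 3247 to 4290, minus strand) had a level of -4.81 ± 0.39 by day (SD, n = 9, detected on 0 arrays) and -3.25 ± 1.28 by night (SD, n = 12, detected on 5). Its fitted difference was -1.87 with a standard error of 0.61 and an adjusted p of 0.869. With day levels set to the lowest detected level of each array its night mean was 2.17-fold higher. That is not a lower bound, since the night mean includes background values from arrays where the target was not detected. NZ_CBZS010000259.1_7178_8143 (positions 7178 to 8143, plus strand) was detected on 0 of 9 day and 4 of 12 night arrays, with a fitted difference of -2.21, a standard error of 0.81 and the same adjusted p. By the same rule its mean was 1.24-fold higher by night, again with background values in the night mean and so not a lower bound. contig00981_8144_8749 (positions 8144 to 8749, plus strand) had -3.71 ± 1.02 by day (SD, detected on 4 of 9) and -4.68 ± 0.77 by night (SD, detected on 3 of 12), with a fitted difference of 1.5 and a standard error of 0.53. The median difference of all 249 targets was -0.26, and it ran from -0.57 to 0.17 under the other scalings. Relative to the median of -0.26 these 3 targets differed by -1.61, -1.95 and 1.77. Of the 10 smallest p, 9 were lower by day.

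Without the station 10 night cast both CBZS targets passed, at -2.81 and -3.63 and an adjusted p of 0.0296, the lowest of their 47 alternatives. Without the station 17 night cast they were at -0.59 and -0.31, and with normexp at -0.24 and -0.28, with adjusted p of 0.947 and 0.806. For contig00981_8144_8749 the difference ran from 0.34 to 1.91 over its 47 alternatives, with a lowest limma adjusted p of 0.0657. Without night surface replicate 3 (station 10 at 1 m) the only target to pass was contig00043_8021_9229, lower by day by a fitted -1.98 at an adjusted p of 0.0420, named here because of that count.

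**Figure D2:**
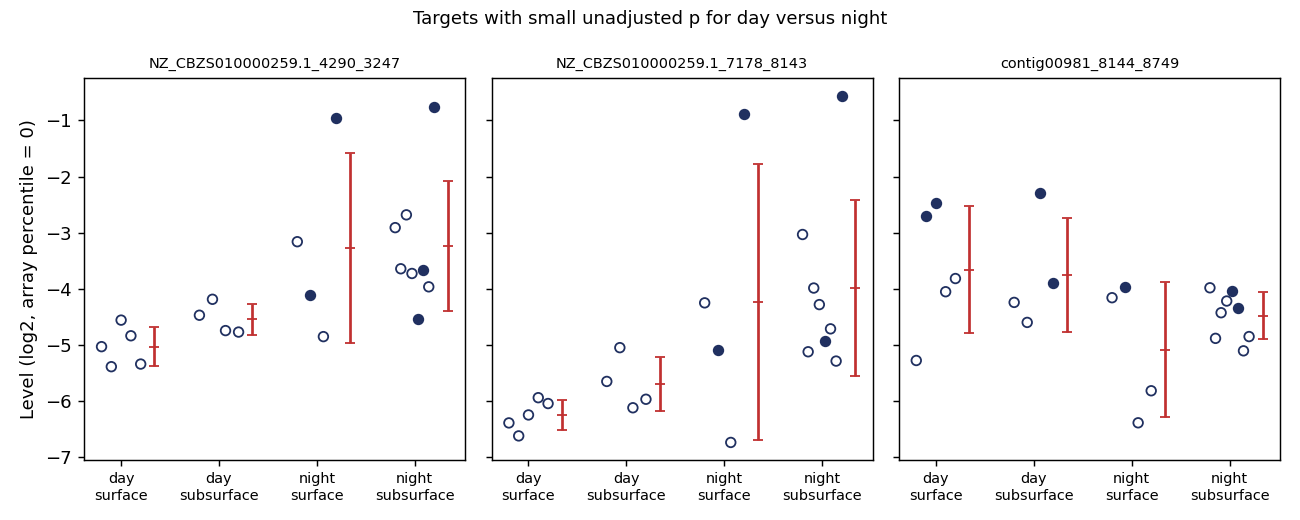
Levels (vertical axis, log2 relative to the array percentile) of the 3 targets printed for day versus night, in the 4 groups, with 1 point per array, filled where the target was detected and open where it was not, and the group mean and SD beside them. The CBZS targets have 0 filled points among the 9 day arrays, and none of the 3 differences passed the threshold.

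As a list, the tested CBZS targets were lower by day relative to the other targets, with a median of -0.50 and 90 members lower and 17 higher. Camera gave an adjusted p of 0.000832, but 0.543 with an estimated correlation. Fry, which tests the list against no change and not against the other targets, gave an adjusted p of 0.478. The 134 unprefixed targets had a median of -0.12, with 87 lower and 47 higher, and stood higher than the others in the camera test (adjusted p = 0.000832), so that median and test differ in sign. Both lists together hold nearly all tested targets, so this call mirrors that of the CBZS list. The unprefixed median was 0.12 with quantile normalization and 0.32 with the percentile over all targets. With an estimated correlation the camera adjusted p of the unprefixed list was 0.516. Fry, against no change, gave an adjusted p of 0.543, with the direction lower. The 6 insertion sequence targets were all below 0 with a median of -0.39, which was 0.16 with normexp (adjusted p = 0.336, and 0.543 with an estimated correlation). In each list 0 targets passed, both over all targets and adjusted over the list alone. The camera calls of both large lists were lost without either night array of station 17, night surface replicate 4 (adjusted p = 0.286) or night subsurface replicate 8 (adjusted p = 0.284). The medians of the CBZS list were -0.13 with quantile normalization and 0.12 with normexp, where the list was still below the other targets.

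In the comparison of surface with subsurface samples 0 of the 249 targets passed in limma, with 2 higher and 34 lower at the surface at an unadjusted p under 0.05, a median difference of -0.24 and a range of that median over the other scalings from -0.05 to 0.07. contig00987_32701_34551 (positions 32701 to 34551, plus strand) had -4.63 ± 0.67 at the surface (SD, n = 9, detected on 2) and -3.74 ± 0.43 below it (SD, n = 12, detected on 7). Its fitted difference was -0.82 with a standard error of 0.22 and an adjusted p of 0.170, and in the deposited value table it was 0.21, of the opposite sign. On the subsurface arrays of slides 1 and 2 this target was not detected and read -3.88 to -2.91, so background values enter its subsurface mean. The surface array of slide 2, not detected either, read -3.36. NZ_CBZS010000341.1_23459_23881 (positions 23459 to 23881, plus strand) was detected on 1 of 9 surface and 2 of 12 subsurface arrays, with a fitted difference of -0.88 and a standard error of 0.25. Relative to the median of all targets these differences were -0.59 and -0.64. All 10 targets with the smallest p were lower at the surface. Layer goes largely with slide within print 2. At stations 10, 11 and 17 the surface arrays were on slide 4 and the deeper ones on slide 5. Station 20 had the reverse, and station 18 had both on slide 5. The main fit, the lists and the sign flips held no slide term, so they do not separate layer from slide. With the cast as a replicate block, 0 targets passed, with 2 higher and 14 lower at an unadjusted p under 0.05. With depth in m in place of the layers 2 targets passed, both lower toward the surface at an adjusted p of 0.0208. They were NZ_CBZS010000341.1_23459_23881, at -0.043 per m toward the surface, and contig00009_69886_69254, at -0.030 per m toward the surface, the latter named because of that count. The CBZS target was detected on only 3 arrays, so its slope rests mostly on values near background.

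In the depth comparison the CBZS list stood higher than the other targets at the surface by camera (adjusted p = 0.00615, and 0.457 with an estimated correlation) although its median was -0.05, with 48 members higher and 59 lower. With quantile normalization its median was 0.17. The unprefixed list stood lower (adjusted p = 0.00725, and 0.457 with an estimated correlation), with a median of -0.34 and 106 members lower against 28 higher. Against no change, fry gave adjusted p of 0.607 for CBZS and 0.102 for unprefixed targets, with the direction lower at the surface for both. The insertion sequence list had a median of -0.30 (camera adjusted p = 0.205, fry 0.102). In each of the 3 lists 0 targets passed, both over all targets and adjusted over the list alone. Within the 8 casts with both layers the mean level at the surface minus below was -0.06 ± 0.94 for CBZS, -0.27 ± 0.51 for unprefixed and -0.36 ± 0.46 for insertion sequence targets (SD, n = 8), with exact sign-flip p of 0.914, 0.172 and 0.0625. For the shares of detected targets the exact sign-flip p were 0.203 for CBZS, 0.508 for unprefixed, 0.5 for insertion sequence and 1 for CAIS targets. Both camera calls were lost without night surface replicate 4 (0.177 and 0.213), without day subsurface replicate 1 (0.0562 and 0.0613), without night subsurface replicate 6 (0.0639 for both), without day surface replicate 3 (0.0664 and 0.0743) and without day surface replicate 5 (0.0561 for both).

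The day and night difference was then compared between the layers. In limma 0 targets passed, with 0 higher and 4 lower at an unadjusted p under 0.05 and a lowest adjusted p of 0.996. For the surface alone 0 passed, with 1 higher and 11 lower by day at an unadjusted p under 0.05, and below it 0 passed, with 0 higher and 4 lower. Without the station 10 night cast 3 targets passed at the surface, the same 2 targets on CBZS contig NZ_CBZS010000259.1 and contig00043_8021_9229, all lower by day at an adjusted p of 0.0365. Without night surface replicate 3 it was contig00043_8021_9229 alone (adjusted p = 0.0278). By camera the CBZS list had a higher day minus night difference at the surface than below it relative to other targets (median 0.11, 62 higher and 45 lower, adjusted p = 3.84e-05). The unprefixed list had a lower one (median -0.25, 31 higher and 103 lower, adjusted p = 5.79e-05). With an estimated correlation both camera adjusted p were 0.288. Fry, which tests against no change, gave adjusted p of 0.981 and 0.483. Without night subsurface replicate 8 the adjusted p were 0.0812 and 0.0927. The 6 insertion sequence targets had a median of -0.46 (camera adjusted p = 0.0892, fry 0.483). Their camera test passed without night subsurface replicate 1 (0.0484), night surface replicate 2 (0.0403) or day subsurface replicate 1 (0.0439).

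Stations were compared within each period. Between night casts 65 of 249 targets differed, 49 of them CBZS (45.8% of those tested), 14 unprefixed (10.4% of those tested) and 2 insertion sequence targets. CBZS targets were among them more often than unprefixed ones (Fisher's exact test, two-sided, p = 5.16e-10, odds ratio 7.18, 95% interval 3.56 to 15.3), with the reservation that targets of a family vary together. The Fisher test was not in the plan. The size of this contrast between the families depended on the scaling, and other settings were not tested for it. CBZS and unprefixed calls were 53 and 48 with quantile normalization, and 52 and 37 with the percentile over all targets. With normexp they were 104 and 119, and 49 and 40 with the deposited values. They were 53 and 22 with the median of detected targets, 67 and 29 with each family centred, and 35 and 3 in print 2 alone. All 49 CBZS targets of the main setting were higher at station 17 than at stations 10 and 21, except that with normexp 45 of 49 were higher than at station 21. These targets were selected because they differed, and their median was 4.33 on the log2 scale over station 10. Over station 21 (1 array, at 21 m) the median was 4.19. Over all tested CBZS targets it was 1.92 over station 10 (94 higher) and 2.07 over station 21 (87 higher). At station 10 34 of the 49 and at station 21 38 were not detected. With those at the lowest detected level of each array the medians were 3.23 (9.38-fold) and 3.15 (8.87-fold). These are lower bounds in the main setting alone. Measured medians of the same targets were lower with quantile normalization (2.81 and 2.87), the deposited values (2.58 and 2.73) and normexp (0.75 and 0.74). They were higher with the median of detected targets and with the percentile over all targets. The direction over station 10 held for 49 of 49 under the 5 other scalings, with normexp giving the smallest median, 0.75. Over station 21 it held for 47 with quantile normalization and in the deposited value table, and for 48 with the percentile over all targets. The night count was 1 without the station 17 night cast (contig01001_11078_11563), 35 without night surface replicate 4 and 100 without night subsurface replicate 1. With normexp it was 230, and on the 16 targets detected on all arrays it was 2.

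Between day casts 17 targets differed, 6 CBZS and 11 unprefixed (Fisher's exact test for the share of each family, two-sided, p = 0.462). Of these 11 were also among the 65 of the night, which does not show a shared station pattern, since both counts use the same residual SD of each target. The target with the smallest p in both periods was contig01001_11078_11563 (positions 11078 to 11563, plus strand; adjusted p 0.000433 by night and 3.51e-06 by day). Its cast mean was 1.70 at station 20, 0.50 at station 17 by day, 0.53 there by night, -0.95 at station 21 and -1.04 at station 18. At stations 9, 10 and 11, where it was not detected, it was -6.88, -5.92 and -6.60. On print 1 it was -2.74 at station 8, and -4.13 at station 19, where it was not detected either. The residual SD for this target was 0.83. Within print 2 alone the day count was 2, contig01001_11078_11563 and NZ_CBZS010000673.1_40604_39870, and the night count 39. All day arrays are on print 2, so this setting removes no day array. It takes the night arrays of print 1 out of the residual spread, on which most of the 17 day calls thus depend. The day count was 63 without day subsurface replicate 4, 42 without day surface replicate 4, 39 without the station 18 cast, and 27 without night surface replicate 3, night subsurface replicate 7 or the station 10 cast. It was 11 without night subsurface replicate 4, night surface replicate 1, day surface replicate 1 or the station 9 cast, 10 without day surface replicate 3, 9 without the station 8 cast and 7 without the station 19 cast.

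The mean of CBZS minus the mean of unprefixed targets within an array, which does not depend on the scaling factor of the array, was 1.28 at station 17 at night. It was -0.16 at station 8, -0.58 at station 19, -0.89 at station 10 and -1.20 at station 21. By day it ran from -1.19 at station 9 and -1.08 at station 11 to 0.18 at station 17. The night casts differed in this measure more than arrays of a cast did (exact rearrangement of the night arrays into casts within each print, p = 0.00381, adjusted over 8 tests 0.0305, smallest possible 0.00190). Neither the measure nor this test was in the plan. For the day casts p was 0.339 by the same exact test, and for the mean of each family alone the lowest p was 0.0724, for insertion sequences by night. Across the 249 targets the median correlation of arrays was 0.858 within a cast (15 pairs) and 0.615 between casts (195 pairs), and within print 2 it was 0.819 (6 pairs) and 0.663 (85 pairs), over targets that are not independent.

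**Figure D3:**
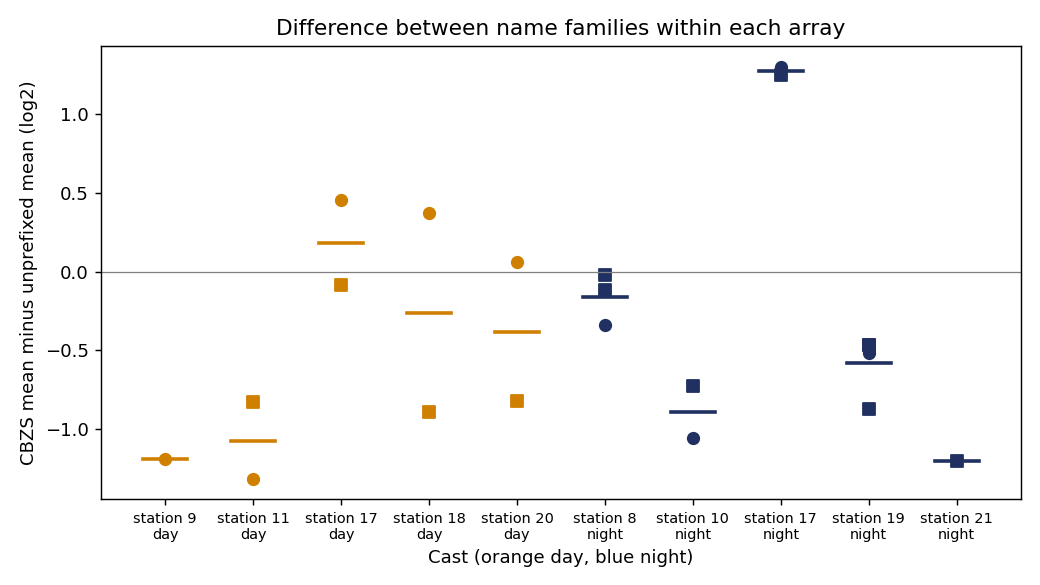
The vertical axis gives the mean log2 level of CBZS targets minus that of unprefixed targets within an array, with 1 point per array (circles surface, squares subsurface), a line at the mean of each of the 10 casts, and casts along the horizontal axis, orange by day and blue by night. The station 17 night cast lies highest, at 1.28, and with normexp the gap between its lower array and the next night array of print 2 falls from 1.98 to 0.49 without changing sign.

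At station 17, the only station with both periods, the levels are given without a test, since there was 1 array per depth and period. CBZS targets were higher by night at both depths, with a median night minus day of 1.73 at 1 m and 1.34 at 25 m by night against 21 m by day over 109 targets, except that with normexp the medians were 0.05 and -0.15. With targets not detected by day at the lowest detected level the medians were 1.35 and 0.58. Counting a target only where it was detected in both periods, or in 1 period with its bound on the same side of 0, 75 of the 109 were higher by night at both depths and 7 lower at both, and for 21 the direction was not shown at 1 depth or both. These targets were all detected at station 17 itself. At 1 m 45 of the 109 were detected by night alone and 63 in both periods, and at the deeper level 53 and 47, with few by day alone. The choice of targets can thus tilt medians and counts toward night. For 99 unprefixed targets the medians were 0.32 and -0.31, with 21 higher and 22 lower at both depths by the same count. Under the other settings the unprefixed medians ran from -0.64 to 0.42 at 1 m and from -0.61 to 0.18 at depth, so their sign was not stable. The CBZS medians ran from 0.05 to 1.84 and from -0.15 to 1.83. The CBZS median exceeded the unprefixed one by 1.41 and 1.65, and by 0.20 and 0.15 with normexp. The normexp offset shrinks differences of dim targets. Whether the offset or the background correction lowered the normexp values was not tested. Detected CBZS targets numbered 126 by night and 64 by day at 1 m, and 106 and 52 at the deeper level. The folds that follow are for the main setting. NZ_CBZS010000259.1_7178_8143 was detected by night alone and was at least 14.3-fold higher at 1 m and at least 13.6-fold higher at depth. NZ_CBZS010000259.1_4290_3247 was at least 12.1-fold and 11.8-fold higher by night. contig00981_8144_8749 was detected by day alone and was at least 5.03-fold and 5.90-fold lower by night. Across the 109 CBZS targets, which are not independent replicates, the night minus day differences at the 2 depths had a Pearson r of 0.886 and a Spearman rho of 0.870, background values of targets not detected included.

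**Figure D4:**
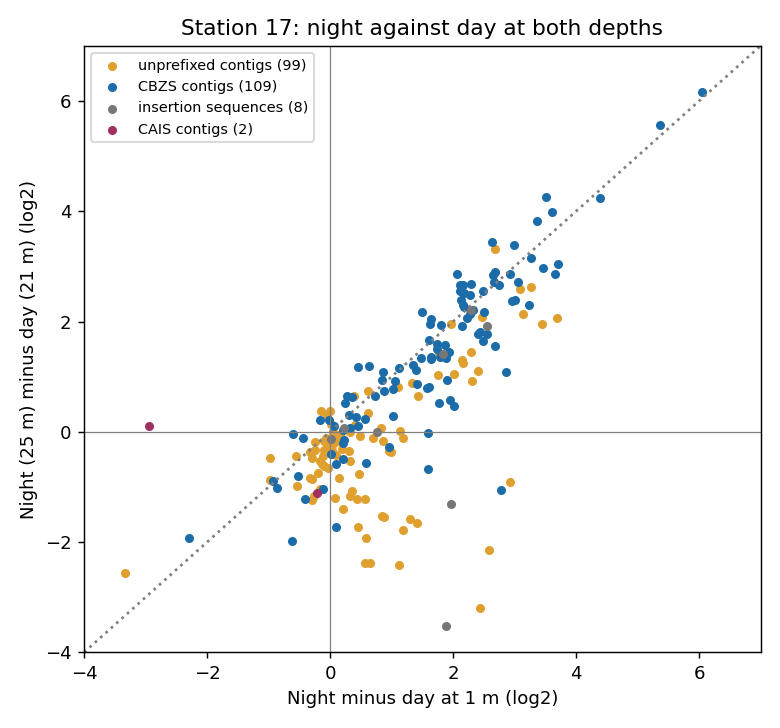
Each point is a target of station 17, with night minus day at 1 m on the horizontal axis and night at 25 m minus day at 21 m on the vertical axis, both log2, coloured by family, and the dotted line marks equal differences. Points of targets not detected in a period use the value measured there, near background. Of the CBZS targets, many of them detected by night alone, 75 of 109 were shown to be higher by night at both depths, while with normexp their medians are 0.05 and -0.15.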

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

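The tests of the station 17 pattern and of neighbouring targets against amount alone were chosen after those results were seen, and the count of splits at an unadjusted p was chosen after the adjusted counts were seen to be 0.

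In 52 groups of values, 4 values stood apart from the others of their group, where chance gives about 1 in 20 groups. At 21 m at station 17 by day, CBZS minus unprefixed targets was -0.0847, against -0.90 to -0.83 on the other 3 day subsurface arrays. On the same array 21.1% of CBZS targets were detected, against 9.76% to 11.4%. At 1 m at station 20 by day, 10.4% of unprefixed targets were detected, against 15.3% to 17.1% on the other 4 day surface arrays. NZ_CBZS010000341.1_23459_23881 was at -3.86 at 37 m at station 18, where it was detected. On the other 3 day subsurface arrays it was not detected, and their -5.76 to -5.67 are values near background, so the size of this gap is not known.

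The day minus night difference of the CBZS and unprefixed lists differed between layers by camera, with adjusted p of 3.84e-05 and 5.79e-05, and neither call held with an estimated correlation (adjusted p = 0.288 for both). Targets present on 1 print alone took no part in the comparisons. Of those on print 1, 30 of 78 CAIS, 29 of 36 CBZS and 39 of 93 unprefixed targets were detected on at least 1 of 7 arrays. Of those on print 2, 17 of 42 CBZS and 14 of 51 unprefixed targets were detected on at least 1 of 14 arrays.

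Other splits of the samples were drawn, 100 per result with the real one included. For day versus night, 45 of 100 splits of the casts gave as many targets at an unadjusted p under 0.05 as the real 9, so chance cannot be excluded. The highest gave 100 targets. That split set stations 8, 9, 10, 11 and 19 against 18, 20, 21 and both casts of station 17. A count this far above the real one points to a structure of the samples other than day and night. Both casts of print 1, stations 8 and 19, were on the same side, but so they are in the real grouping, where print is a term of the fit. What the structure follows was not tested. For the difference between layers 66 splits gave as many as the real 4 (highest 81), for the surface 41 gave as many as 12 (highest 103), and below it 57 gave as many as 4 (highest 47). For the surface against the subsurface, 11 splits within casts gave as many as 36 (highest 66). Chance cannot be excluded for any of these. The same holds for the lists. A camera p as small as the real 0.000357 for CBZS by day and night came from 54 splits (smallest 5.69e-15) and one as small as 0.000555 for unprefixed from 56 (smallest 3.25e-15). By depth, 27 splits reached 0.00205 for CBZS (smallest 5.31e-11) and 31 reached 0.00484 for unprefixed (smallest 2.18e-11). For stations the arrays were rearranged into casts. By night 1 of 100 splits, the real one, gave as many as 95 targets at an unadjusted p under 0.05 (highest other 88). By day 2 of 100 gave as many as 59 (highest other 72). Both lay under the bound of 5 in 100 set against chance. By day another split exceeded the real count, and the day calls rest on a residual spread that includes night arrays. With targets past the adjusted threshold, which were counted earlier, the numbers of splits were again 1 (real 65, highest other 51) and 2 (real 17, highest other 38).

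CBZS targets were higher at station 17 at night than in the other night casts of print 2. A scaling factor of the 2 arrays is argued against by the difference between families within an array. Its lower station 17 value exceeded the highest other night array by 1.98, by 1.71 with quantile normalization and by 0.49 with normexp, the last just under the 0.5 set as the bound. Brightness over background is not cancelled by this difference and stays open. The 2 arrays had 243 and 206 detected targets, against 99 to 128 on the other night arrays of print 2. On slide 3, with 280 and 243 detected, the difference was lower, -0.12 and -0.34, but those arrays are of another print and station. The slide is argued against by an excess over the station 10 array of the same slide of 3.20 on slide 4 and 1.61 on slide 5. More of the organism alone would raise its targets alike. Over 14 CBZS targets detected on all 4 night arrays of stations 17 and 10 the difference correlated between the 2 depths with a Pearson r of 0.758 (one-sided permutation p across targets 0.0027). At 1 m they ran from -0.31 to 4.69 with a median of 1.35 and 11 of 14 higher at station 17. At 21 to 25 m the median was -0.12 with 5 of 14 higher, so at depth these targets did not follow the pattern. Only 1 of the 14 is among the 49 called at night, most of which were not detected at station 10, so the test does not reach them and greater amount alone stays open. The requirement that most of the targets be among those called was added after this overlap was seen. The test was run earlier on night minus day at station 17, with an r of 0.888 over 42 targets, and was replaced because the pattern is one between stations. Greater amount together with unequal change, a difference between stations in the community or its state, and binding of transcripts from other organisms in the plankton stay open and were not tested.

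Few targets were detected on the 5 arrays of slides 1 and 2, with a median of 43 against 116 on print 2. A higher background on those slides could lower the count. Above 1 common normalized level the medians were 24 and 29.5, between the bounds set for and against it. Above 1 common raw level they were 23 and 20.5, as a higher background would give, but at station 8 the array on slide 1 then had 30 against 48 and 50 on slide 3. The levels disagree, so the background and the water of station 19 cannot be told apart. All 4 arrays of that station are on slide 2. At station 8 the array at 25 m, on slide 1, had 43 detected targets against 280 and 243 on slide 3, while above the common normalized level it had 41 against 37 and 36.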

How the results depend on the processing

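The alternatives for stations, for the separate layers and for station 17, normexp and the percentile over all targets for the lists, the common floor and the fits without slides 1 and 2 were added after the data were seen. No paired analysis was possible because the replicate numbers follow the order of deposit, except by cast, and with the cast as a replicate block 0 targets passed for depth. Function lists and the comparison between genomes were not run. The cause of the changes below was not tested, except that fewer targets or casts were tested where the setting removes them. Signal over background limits all counts, as 375 of 747 targets were detected on no array.

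Counts past the threshold stayed at 0 in 47 of 49 alternatives for day versus night (0 to 2 leaving out arrays or casts), in 45 of 47 at the surface (0 to 3), in all 47 below it and for the difference between layers, and in 49 of 50 for depth, where depth in m gave 2. contig00987_32701_34551 by depth reversed to 0.21 in the deposited value table. Station counts were 39 by night and 2 by day in print 2 alone, 2 and 1 on targets detected on all arrays, and 28 and 1 with a common floor. By night they were 104 with quantile normalization, 100 with each family centred and 230 with normexp. By day they were 29 with no filter and 6 without slides 1 and 2. Leaving out arrays or casts gave 1 to 100 by night and 7 to 63 by day.

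With an estimated correlation the list p were 0.543 (CBZS) and 0.516 (unprefixed) for day versus night, 0.457 for both by depth and 0.288 for both between layers. Insertion sequences reversed by day and night with normexp (0.604) and passed between layers without slides 1 and 2 (0.0152). Leaving out single arrays gave adjusted p of 3.33e-08 to 0.286 for CBZS and unprefixed by day and night, 3.63e-05 to 0.177 and 5.10e-05 to 0.213 by depth, and 1.62e-08 to 0.0812 and 2.71e-08 to 0.0927 between layers. For insertion sequences the ranges were 0.211 to 0.525, 0.124 to 0.396 and 0.0403 to 0.262. Shares of detected targets kept their direction and side in both alternatives.

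At station 17 the CBZS medians were 0.66 with quantile normalization and 0.78 with the percentile over all targets at 1 m, 0.053 and -0.15 with normexp, and 0.61 and 0.61 in the deposited table. Unprefixed medians at 1 m were -0.49 and -0.64 with quantile normalization and the percentile over all targets.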

Other observations

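Targets were also grouped by contig, for 18 contigs with at least 3 tested targets, and these lists and the tests of neighbours against amount alone were chosen after the data were seen. All 6 tested targets of contig00009 were lower at the surface than below it, with a median of -0.78, and so were all 4 of contig01275, with a median of -0.66. Their adjusted p over the 18 contigs were 0.00940 and 0.0184 by camera, 0.0242 and 0.00816 by fry, and 0.161 and 0.144 by camera with an estimated correlation. All 8 tested targets of contig00043 had lower levels by day, with a median of -1.05. The camera adjusted p was 0.00391, with an estimated correlation 0.741, and by fry 0.521. The median of all tested targets was -0.24 by depth and -0.26 by day and night.

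Targets that lie near each other on a contig varied together across the 14 arrays of print 2. The median correlation over 58 pairs less than 2000 bases apart was 0.787, against 0.665 for 83 pairs farther apart on the same contig and 0.311 for pairs of the same family on different contigs. Pairs on different contigs can mix organisms, so amount of the organism was weighed within contigs. The difference there of 0.122 had a one-sided permutation p of 0.19, with positions shuffled within each contig, so amount of the organism alone stays open. The test was run earlier against pairs on different contigs, with a difference of 0.476 (permutation p = 1e-04, the smallest that the resampling can give), and was replaced for that reason. Joint transcription of neighbours on the same strand may contribute, as a hypothesis. Pairs on the same strand had a median of 0.798 and pairs on opposite strands 0.465. The difference of 0.33 had a permutation p of 0.13 with only 5 opposite pairs, which keeps it open.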
